A study of Homo sapiens with 8 samples.

How the data were processed

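RNA from L363 cells, an established human plasma cell line, was measured on 8 2-colour spotted microarrays. Each array carried Cy5-labelled cDNA from cells given 12.5 µM MLN120B and Cy3-labelled cDNA from cells given the solvent DMSO, per the labels. MLN120B is a small-molecule inhibitor of IKKβ, the kinase that releases NF-κB by marking its inhibitors for destruction. Treatment lasted 8 h on 2 arrays, 12 h on 3 and 24 h on 3, at 37 °C per the labels' protocols. Total RNA was extracted with TRIzol, per the same protocols. No array had the dyes exchanged, so a dye bias of a feature cannot be separated from the treatment. Nothing in the labels says that samples of a time came from separate cultures, so p-values measure only the spread between these samples, which may be technical.

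The values analysed were the authors' deposited log2 ratios of the 2 channels, 1 column per array, for 15246 array features, of which 14771 had a value on at least 1 array. The base was read from the values: the largest size, 12.4, exceeds what a natural log ratio (11.1) or a log10 ratio (4.82) of 16-bit intensities can reach. That size occurred on sample 2 at 8 h alone. On the other arrays the largest sizes ran from 1.93 to 10.8, which a natural log ratio can reach. That all arrays share base 2 is therefore an assumption. The authors' background correction, spot filter, normalization and centring are not given in the sources used here. The direction, Cy5 over Cy3 and so MLN120B over DMSO, is likely but not stated; it rests on the labels, which set treated cells in Cy5 against solvent, and on the usual red over green convention. If the sign were turned, every direction given would reverse and all sizes and counts would stay. No signal intensities were used here, so signal over background is unknown, and the number of arrays limits the precision.

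Array medians of the deposited values, in the order of samples 1 and 2 at 8 h, were 0.001 and -0.096. They were -0.38, -0.006 and -0.15 for samples 1, 2 and 3 at 12 h, and -0.48, 0.001 and -0.0055 for samples 1, 2 and 3 at 24 h. Each array was centred on its median. The platform annotation paired 10169 features with 1 gene, 4 with several and 5073 with none listed. Symbols were updated for 10128 features through Entrez identifiers and for 17 through accessions, using RefSeq gene names of the GRCh38.p14 assembly for names alone, and 24 were kept as listed. Features of a gene were averaged on each array, and unnamed features stayed apart. A row was tested when it had values on at least 2 arrays at each time, which left 5411 rows, 3311 of them named genes and 3460 with values on all 8 arrays. No build is named, and no coordinates are given.

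A linear model with a mean for each time was fitted to all 8 arrays with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, 5 residual degrees of freedom). The DMSO RNA served as the control on every array, so the ratio was tested against 0, which leaves out the control's own spread. The contrasts were the mean over the 3 times, each time, and the 3 differences between times. All tests were 2-sided, and p-values were adjusted by Benjamini-Hochberg over the rows, with a threshold of 0.05. Camera's statistic was applied to moderated z-values for 28 gene lists with at least 5 tested members, at a preset correlation of 0.01, for the mean and for 24 h against 8 h. It was repeated with a correlation estimated from the residuals, and fry was run, both on rows with values on all 8 arrays. List medians per array were compared with 0 by an exact sign-flip test. Python 3.11.15 with pandas 2.3.3 and matplotlib 3.10.9 prepared the table and the plots.

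Groups, designs, lists, most alternatives and the rule for named genes were fixed before the data were examined. The rule took all measured genes of the NF-κB study list, the 3 named genes with the smallest p for a contrast in which no row passed, and, for each other list with no member past the threshold, the 2 members with the largest mean change; IKBKB, the gene of the inhibitor's target, was to be given in every case, but no feature was annotated to it, and it may be among the features with no gene listed. The NF-κB study list is a signature remembered from the study's own paper, where it was chosen in part on these arrays. The numbers in the database identifiers of the labels fall into 3 runs of consecutive values, called database runs here: run 1 holds sample 3 at 12 h and 24 h, run 2 holds sample 2 at 8 h and sample 1 at 12 h and 24 h, and run 3 holds sample 1 at 8 h and sample 2 at 12 h and 24 h. Alternatives were the values as deposited, quantile and scale normalization, other filters on missing values, features on their own, sample number as a block, database run as a fixed or random block, 1 mean per database run, array weights, robust variances, each array left out, and the list tests named above. Those added later are given with their results.

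The fit was tested on simulated data with the real spread of rows and arrays but independent arrays. For the mean over 3 times, 200 of 5411 rows were moved by a log2 of 1, 2 or 4. It recovered 76.1%, 98.5% and 100% of them, with 0 calls among 5211 unmoved rows. Where all arrays had equal scales it recovered 74.6%, 95.5% and 100%, with 9 false calls. Over 1400 camera tests of the 28 lists in 50 simulations with no change, 4.14% had p under 0.05, and a list of 10 members moved by -0.5 was called in 50 of 50. Correlation between genes or within database runs was not simulated. With 200 rows moved, the Benjamini-Hochberg adjustment is milder than where few rows change. The recovered shares therefore do not hold for data with few changed rows.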

Results

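The data describe how gene expression in L363 myeloma cells differed after 8 h, 12 h or 24 h with the IKKβ inhibitor MLN120B from that in cells given DMSO alone, in 2, 3 and 3 samples. Many myelomas carry active NF-κB signalling, and the series title places these arrays in a study of that pathway. Each sample was read on its own array against DMSO-treated cells, and values are log2 ratios centred on the array median, likely MLN120B over DMSO, so that negative values mean lower with the inhibitor. Arrays held values for between 6344 features (sample 1 at 24 h) and 13007 features (sample 2 at 12 h). Their spread differed widely. The SD over features was 0.21, 0.25 and 0.28 in database run 3, 0.58 and 0.35 in run 1, and 1.42, 1.31 and 1.00 in run 2. Over genes, arrays of the same run correlated at 0.12 to 0.57 (Pearson, 7 pairs), arrays of different runs at -0.21 to 0.096 (21 pairs), and arrays of the same time at -0.11 to 0.096 (7 pairs); genes are not independent replicates.

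NF-κB target genes of the study list were lower in inhibitor-treated cells over the 3 times. NFKBIA, which encodes the inhibitor IκBα that NF-κB itself induces, fell by 0.93 ± 0.14 on the log2 scale (SE, n = 8), and TNFAIP3, which encodes the feedback regulator A20, fell by 0.84 ± 0.18. NFKB2, the precursor of the p52 subunit, fell by 1.31 ± 0.33, WNT10A, a secreted Wnt ligand, fell by 0.71 ± 0.17, and MALT1, the paracaspase of antigen receptor signalling, fell by 0.49 ± 0.17. CD74, the MHC class II invariant chain, fell by 0.58 ± 0.23, and IL2RG, the common cytokine receptor chain, fell by 0.42 ± 0.13. RELB, a subunit of the alternative pathway, at -0.43 ± 0.19, NFKBIE, which encodes IκBε, at -0.77 ± 0.33, and PLEK, at -1.10 ± 0.84, did not pass. The ratio of PLEK rested on -8.93 on sample 1 at 12 h. NFKBIE was at -3.27 on sample 1 at 24 h, and its mean was -0.44 without that array. The size for NFKB2 varied by run: -2.54, -2.39 and -2.35 in run 2, -0.70 and -1.21 in run 1, and -0.15, -0.38 and -0.71 in run 3. Its 3 features with 6 or more values had means from -1.48 to -0.29.

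Of the 11 genes of this list 10 were measured, all with a mean below 0, and no feature was annotated to BIRC3, though 5073 features had no gene listed. Adjusted over the list alone, 7 passed in limma's test, from adjusted p = 0.00085 for NFKBIA to 0.049 for CD74, and over all rows 0 passed, the smallest adjusted p being 0.46. Because the study chose the list in part on these samples, neither its direction nor this count is independent evidence. The list's median was -0.74 and camera's adjusted p was 1.8e-12 with the preset correlation. The call was lost otherwise: adjusted p = 0.41 with an estimated correlation, and fry gave an adjusted p of 0.13. On the arrays the list's median averaged -0.67 ± 0.44 (SD, n = 8) and lay below 0 on 8 of 8 (exact sign-flip p = 0.0078, the smallest that 8 arrays allow, adjusted over 28 lists 0.073). Arrays of a run resemble each other, and 3 runs allow no p under 0.25.

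Within runs, the array medians of the study list averaged -0.85 in run 1, -0.94 in run 2 and -0.27 in run 3, and with the run as a block the list's median was -0.73. The list's median was -0.49 with array weights, which limma estimates from deviations from the time means. Samples 1 and 2 at 8 h received the same weight, 0.72, though their SDs were 0.21 and 1.42. Without run 2, the widely spread arrays, the list's median was -0.47, a setting added after the data were seen.

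**Figure D1:**
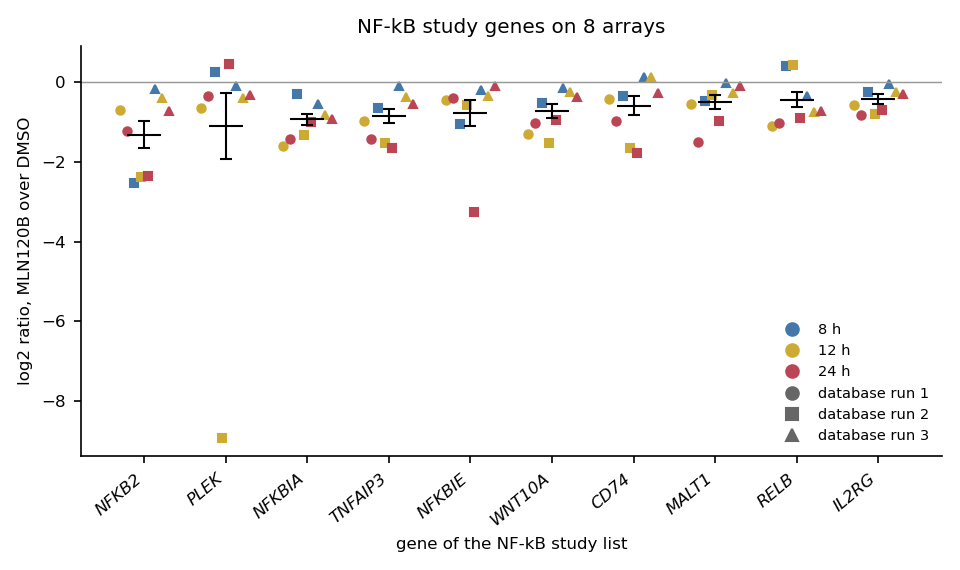
Log2 ratios, likely MLN120B over DMSO, of the 10 measured genes of the NF-κB study list on 8 arrays. Each symbol is an array, coloured by treatment time and shaped by database run, and the black bar is the fitted mean over the 3 times with its SE; NFKBIA lies below 0 on 8 of 8 arrays, and PLEK has a single value of -8.93.

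Textbook NF-κB targets outside the study list showed no common shift over all 8 arrays, where run 2 lay opposite to runs 1 and 3. The median of 38 measured members was 0.0091 (camera adjusted p = 0.96; 18 below 0, 20 above), and 0 passed over all rows or adjusted over the list alone. SDC4, the proteoglycan syndecan-4, was at 1.01 ± 0.48 and CFLAR, the caspase-8 inhibitor c-FLIP, at -0.60 ± 0.25 (SE, n = 8). The array medians of this list averaged -0.13 in run 1, 0.20 in run 2 and -0.054 in run 3. They lay below 0 on 5 of 8 arrays, and those above 0 were all of run 2. The sign of the list's median turned under 14 of 28 alternatives. Without run 2 it was -0.098 with a camera adjusted p of 0.00026, the only alternative that gave a call. Among the pathway's kinases, adaptors and receptors, 16 measured, the median was -0.11 (adjusted p = 0.63), with TNFRSF17, the plasma cell receptor BCMA, at 0.48 ± 0.16 and the deubiquitinase gene CYLD at -0.33 ± 0.19.

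MHC class II genes were lower in inhibitor-treated cells as a group over the 3 times, though not at 8 h, where the median was 0.061 with 7 of 11 members above 0. Of 11 measured members 9 had a mean below 0, with a median of -0.26 (camera adjusted p = 0.00068; adjusted p = 0.47 with an estimated correlation). HLA-DRA was at -0.64 ± 0.19 and CD74, which the NF-κB study list also holds, at -0.58 ± 0.23 (SE, n = 8); adjusted over the list alone 0 passed, and over all rows 0. Without sample 1 at 8 h the median was -0.18 and the call was lost (adjusted p = 0.35), as it was without run 3 (-0.26, adjusted p = 0.23). The array medians lay below 0 on 7 of 8 arrays (exact sign-flip p = 0.031, adjusted over 28 lists 0.175). The array medians averaged -0.36 in run 1, -0.50 in run 2 and -0.18 in run 3. With the run as a block the list's median was -0.26 (camera adjusted p = 0.0060, which leaves out the spread between runs). The list's median was -0.16 with array weights and -0.47 after quantile normalization.

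Genes of the endoplasmic reticulum and of the ribosome lay above the array median as groups, and passed only in camera with the preset correlation. Of 15 genes of the unfolded protein response and its chaperones 13 had a mean above 0, with a median of 0.16 (camera adjusted p = 0.0039; adjusted p = 0.47 with an estimated correlation). SSR3, a subunit of the translocon-associated complex, rose by 0.64 ± 0.15 (SE, n = 8) and passed adjusted over the list alone (adjusted p = 0.025), as 1 of 15; over all rows 0 passed. HSP90B1, the chaperone GRP94, was at -0.45 ± 0.31, and at -0.17 without sample 3 at 12 h, where it was -2.82. Of 17 ribosomal protein genes 15 lay above 0, with a median of 0.16 (adjusted p = 0.0014; adjusted p = 0.47 with an estimated correlation), among them RPS6 at 0.63 ± 0.25 and RPL37 at 0.49 ± 0.26, and 0 passed over all rows or adjusted over the list alone.

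The endoplasmic reticulum list averaged 0.50, 0.19 and 0.097 over the array medians of runs 1, 2 and 3, and the ribosomal list 0.44, 0.078 and 0.057. With the run as a block the medians were 0.21 (camera adjusted p = 0.0091) and 0.18 (camera adjusted p = 0.00068), p-values that leave out the spread between runs. Both calls were lost without run 1, at medians of 0.077 and 0.088 (adjusted p = 0.12 for both). The first was also lost without sample 3 at 24 h (0.11, adjusted p = 0.053) or sample 1 at 8 h (0.14, adjusted p = 0.35) and without run 3 (0.18, adjusted p = 0.23), and the second without sample 3 at 12 h (0.13, adjusted p = 0.072). On the values as deposited, whose median over all rows lies at -0.12, the list medians were 0.029 and 0.027, and they passed.

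**Figure D2:**
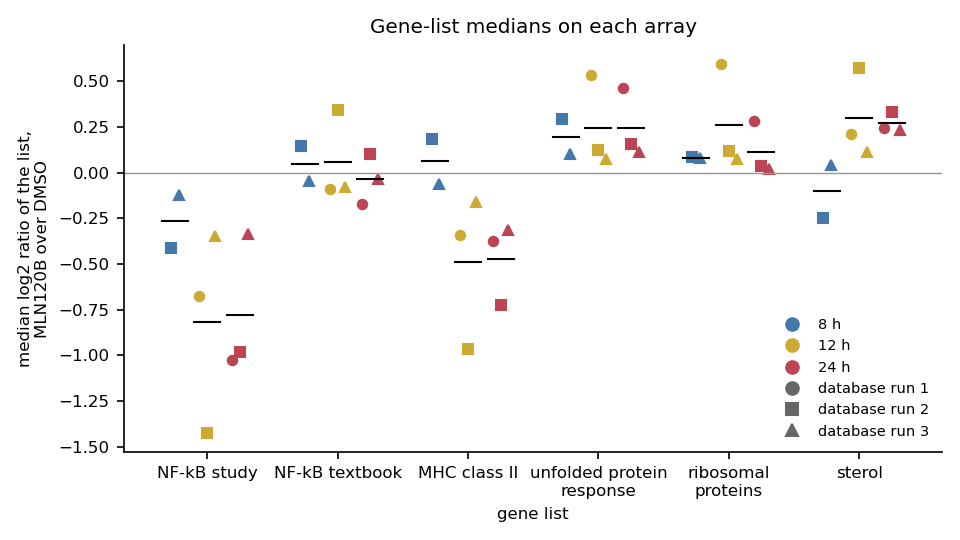
Median log2 ratio, likely MLN120B over DMSO, of 6 gene lists on each array, grouped by treatment time (colour), with the database run as the symbol shape; black bars are means over the arrays of a time. The NF-κB study list lies below 0 on 8 of 8 arrays, and MHC class II medians average 0.061 at 8 h and -0.47 at 24 h.

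No other list passed over the 3 times. Sterol and fatty acid synthesis genes had a median of 0.16 over 10 members (camera adjusted p = 0.11); INSIG1, which restrains sterol synthesis, rose by 0.58 ± 0.15 (SE, n = 8) adjusted over the list alone (adjusted p = 0.045), the only member to do so, and SREBF2, the sterol regulator, was at -0.42 ± 0.19. At 24 h alone, a time for which no list test was planned, the sterol list passed with a median of 0.31 (adjusted p = 0.0021; adjusted p = 0.33 with an estimated correlation). Genes that plasma cells lower from the B cell stage had a median of 0.091 (adjusted p = 0.14), with EBF1 at 0.48 ± 0.28 and SPIB at 0.34 ± 0.25. Plasma cell genes had a median of 0.044 (adjusted p = 0.63), with ELL2, an elongation factor of antibody secretion, at -1.11 ± 0.50 (-3.15 on sample 2 at 8 h and -3.55 on sample 1 at 12 h, and -0.31 to 0.22 on the other arrays) and SLAMF7 at -0.46 ± 0.27. MHC class I presentation and immunoproteasome genes, of which the HLA genes share near-identical sequences, had a median of -0.065 (adjusted p = 0.63), with HLA-G at -0.86 ± 0.38 and PSMB9 at -0.50 ± 0.24.

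Proliferation and survival lists did not pass either. Medians were 0.0068 for G2 and mitosis genes (camera adjusted p = 0.96; PLK1 -0.39 ± 0.21, AURKB -0.35 ± 0.22) and -0.083 for DNA replication genes (adjusted p = 0.36; MCM4 -0.40 ± 0.22, CDT1 -0.34 ± 0.25). Targets of MYC had a median of 0.080 (adjusted p = 0.18), MYC itself being at 0.34 ± 0.13 and NCL at -0.53 ± 0.38. Apoptosis regulators had a median of -0.064 (adjusted p = 0.20), with BMF, a pro-apoptotic BH3-only gene, at -0.69 ± 0.20. Targets of p53 stood at -0.0060 (adjusted p = 0.997; TP53INP1 -0.54 ± 0.32) and cell cycle inhibitors at -0.10 (adjusted p = 0.50; CDKN1A -0.36 ± 0.24, CCNG2 0.33 ± 0.20).

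Stress and signalling lists gave medians of -0.029 for amino acid stress (camera adjusted p = 0.86; SLC7A5 -0.50 ± 0.26, CBS -0.35 ± 0.19), 0.025 for heat shock (adjusted p = 0.72; HSPA1A 0.26 ± 0.16, HSPA1L -0.23 ± 0.23) and -0.087 for hypoxia and glycolysis (adjusted p = 0.81; BNIP3L 0.72 ± 0.26, ALDOA -0.56 ± 0.26). Interferon-induced genes stood at -0.050 (adjusted p = 0.96; BST2 -0.40 ± 0.27, IRF9 -0.32 ± 0.17) and immediate early genes at -0.048 (adjusted p = 0.96; EGR1 0.76 ± 0.34, IER5 -0.50 ± 0.20). Proteasome subunits stood at -0.064 (adjusted p = 0.81; PSMD14 -0.073 ± 0.14, PSMB4 -0.070 ± 0.23), and adhesion and growth factor genes at 0.028 (adjusted p = 0.95; IL10 1.32 ± 0.65, ITGB7 0.66 ± 0.21).

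Markers of other cell types and control genes showed no shift that passed. Medians were 0.082 for T cell markers (camera adjusted p = 0.87; GATA3 -0.75 ± 0.54, CD3D -0.62 ± 0.48), 0.065 for myeloid markers (adjusted p = 0.95; CD68 -0.50 ± 0.29, TYROBP 0.24 ± 0.16) and 0.067 for erythroid and megakaryocyte markers (adjusted p = 0.63; HBG1 0.12 ± 0.12, KLF1 0.091 ± 0.14). Stroma markers stood at 0.049 (adjusted p = 0.50; LEPR -0.54 ± 0.23, BGN 0.45 ± 0.28), and housekeeping genes at -0.14 (adjusted p = 0.34; ACTB -0.47 ± 0.21, ACTG1 -0.36 ± 0.15). Without run 2 the sign turned for SDC4, SLAMF7, EBF1, SPIB, CBS, MCM4, CDT1, NCL, CDKN1A, CCNG2, PSMD14, IL10, GATA3 and CD3D. After quantile normalization it turned for SPIB, NCL, HBG1 and KLF1, and for PSMB4 it turned under 7 alternatives. Many of these means depend on 1 array: of 62 means of named genes over the 3 times, 42 came out smaller by over 1.5 times, or with the other sign, when 1 array was left out, 26 of them without sample 2 at 8 h and 20, in part the same, without sample 1 at 12 h, both of run 2. Genes named for the mean over 3 times had values on 8 arrays, except BMF, ELL2, SPIB, SLC7A5, EGR1, TYROBP, KLF1 and BGN, with 7. The mean of a list differed in sign from its median for T cell (-0.069) and myeloid markers (-0.010), plasma cell genes (-0.012), G2 and mitosis genes (-0.024) and NF-κB textbook targets (-0.0058).

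Gene by gene, no row passed over the 3 times. The named genes with the smallest p were NFKBIA, TNFAIP3 and NEK6, a mitotic kinase gene at -0.62 ± 0.13 (SE, n = 8). Of 5411 rows limma called 0, and 184 had an unadjusted p under 0.05 where 271 would arise by chance alone. With the database run as a block 6 rows passed, among them NFKB2 at -1.25 ± 0.12 (adjusted p = 0.039) and RXRB at -2.98 ± 0.15 (adjusted p = 0.039), the others being unnamed features; RXRB was chosen after its value was seen. This block takes differences between runs out of the error, so these SEs and p-values leave out the spread between runs. With the run as a random block, or with 1 mean per run, 0 rows passed. Quantile normalization gave 6 rows, and the fit without sample 1 at 8 h 58.

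At 8 h the NF-κB study list averaged -0.27 ± 0.21 over the array medians (SD, n = 2), with NFKBIA at -0.42 ± 0.27 and TNFAIP3 at -0.38 ± 0.36 (SE). Adjusted over the list alone 0 of 10 passed. Over all 5411 rows limma called 0, with 130 at an unadjusted p under 0.05. The named genes with the smallest p were SURF1 at -4.69 ± 1.55, SIT1 at 5.00 ± 1.66 and SCFD1 at 2.18 ± 0.75, and their SDs over the 2 arrays were 6.42, 6.88 and 2.84; without sample 2 they were at -0.15, 0.13 and 0.17. Without sample 1, which leaves the lone array of run 2 at this time, 131 rows passed.

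At 12 h the study list averaged -0.82 ± 0.55 over the array medians (SD, n = 3). Adjusted over the list alone 3 of 10 passed: NFKBIA fell by 1.25 ± 0.22 (SE), TNFAIP3 by 0.95 ± 0.29 and WNT10A by 1.02 ± 0.28. Over all rows limma called 0, with 166 at an unadjusted p under 0.05. Besides NFKBIA the smallest p belonged to BMF at -1.25 ± 0.30 and GLCCI1 at -1.16 ± 0.30.

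At 24 h the study list averaged -0.78 ± 0.38 over the array medians (SD, n = 3). Adjusted over the list alone 9 of 10 passed, PLEK being the exception. Among the 9, NFKBIA fell by 1.11 ± 0.22 (SE), TNFAIP3 by 1.20 ± 0.29, CD74 by 1.01 ± 0.38 and RELB by 0.88 ± 0.30. NFKBIE passed with -3.27 on sample 1, against -0.096 on sample 2 and -0.40 on sample 3. The study list was chosen in part on these samples, so this count and that at 12 h are not independent evidence. HLA-DRA, an MHC class II chain, fell by 1.20 ± 0.31 and was 1 of 11 MHC class II genes to pass adjusted over that list alone. Over all rows limma called 0, with 109 at an unadjusted p under 0.05. After NFKBIA the smallest p belonged to MIR155HG, the host gene of miR-155, at -1.09 ± 0.22, and ITGB7, the integrin β7 gene, at 1.45 ± 0.34. Quantile normalization gave 5 rows.

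The NF-κB study list and MHC class II genes were lower at 24 h than at 8 h as groups. For the study list 10 of 10 members had a difference below 0, with a median of -0.62 (camera adjusted p = 0.0064; adjusted p = 0.74 with an estimated correlation), CD74 differing by -0.90 ± 0.59 and RELB by -0.92 ± 0.48 (SE). For MHC class II 11 of 11 were below 0, with a median of -0.58 (adjusted p = 0.00075; adjusted p = 0.74 with an estimated correlation), and HLA-DRA differed by -1.09 ± 0.48. Within runs 2 and 3, each with 1 array per time, the list medians differed by -0.57 and -0.22 for the study list and by -0.91 and -0.25 for MHC class II.

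With the run as a block the 24 h against 8 h medians were -0.63 (adjusted p = 0.0043) and -0.62 (adjusted p = 0.00079). The study list's call was lost without sample 1 at 8 h (-0.37, adjusted p = 0.71), sample 1 at 24 h (-0.47, adjusted p = 0.11) or sample 3 at 24 h (-0.45, adjusted p = 0.20), and also with the sample number as a block (-0.63, adjusted p = 0.20), with array weights (-0.45, adjusted p = 0.17), without run 1 (-0.45, adjusted p = 0.23) and without run 3 (-0.77, adjusted p = 0.22). The MHC class II call was lost without sample 1 at 8 h (-0.65, adjusted p = 0.062). Quantile normalization gave -1.09 for the study list, and leaving out run 2 gave -0.30 for MHC class II. Sterol genes had a median difference of 0.43 (camera adjusted p = 0.070).

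Limma called no single gene different between times. Each comparison had fewer rows at an unadjusted p under 0.05 than the 271 expected by chance alone. The absence of calls therefore does not show that ratios were equal. For 24 h against 8 h limma called 0 of 5411 rows, with 44 at an unadjusted p under 0.05; MIR155HG differed by -1.08 ± 0.35, CSTF3 by -1.09 ± 0.41 and ITGAL, the integrin αL gene, by 1.39 ± 0.50 (SE). For 12 h against 8 h it called 0, with 64; GPBP1 differed by -1.75 ± 0.56, LYSMD3 by -1.42 ± 0.47 and SMC6 by -1.45 ± 0.49. For 24 h against 12 h it called 0, with 37; CSTF3 differed by -1.05 ± 0.36, MIR155HG by -0.89 ± 0.31 and PPP1R15B, a phosphatase subunit that reverses eIF2α phosphorylation, by -1.17 ± 0.41. Some of these differences depend on 1 array of run 2: without sample 2 at 8 h ITGAL differed by 0.52 at 24 h and GPBP1 by -0.89 at 12 h, and without sample 1 at 24 h CSTF3 differed by -0.70 from 12 h. Without sample 1 at 8 h, 78 rows passed for 12 h and 77 for 24 h against 8 h.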

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

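All tests in this part were chosen after the results were seen, apart from the list tests at 24 h against 8 h and the counts over other splits of the arrays.

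The NF-κB study list and the MHC class II list were singled out because their ratios differed between times. At 12 h against 8 h the list medians differed by -0.52 for the study list (camera adjusted p = 0.038) and by -0.50 for MHC class II (adjusted p = 0.0027). At 24 h against 8 h they differed by -0.62 (adjusted p = 0.0064) and -0.58 (adjusted p = 0.00075). With an estimated correlation none of these 4 differences passed in camera, at adjusted p = 0.79 and 0.74 for the earlier and the later comparison of both lists. Within runs 2 and 3, each with 1 array per time, the study list differed by -1.01 and -0.23 at 12 h against 8 h. MHC class II differed by -1.15 and -0.10, so the larger differences lay in the widely spread run 2.

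The study list lay below 0 on 8 of 8 arrays. It was chosen in part on these arrays, so tests of whether its genes lie below 0 on them decide nothing, and noise of the widely spread arrays of run 2, errors of single spots and chance stay open. The values are: a median of -0.47 without run 2 (camera adjusted p = 2.8e-12 with the preset correlation), 36 of 36 features with 6 or more values below 0 and 43 of 45 with any value, and in 1 of 100 sign flips of whole arrays, the real one, a median as large as 0.74, against 0.69 in the highest other. A dye bias of these genes stays open too, since no dyes were exchanged. Only a dye bias equal on all arrays forbids a difference between times, and whether it is equal is unknown. The difference between times did not pass in camera with an estimated correlation (adjusted p = 0.74), so it decides nothing here. An effect of the inhibitor is another open explanation, and these arrays cannot separate it from the dye.

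MHC class II genes were lower at 24 h than at 8 h. The median difference did not rest on CD74 alone, which the NF-κB list shares: without CD74 it was -0.48 (camera adjusted p = 0.0020). With the run as a block the median was -0.62 (camera adjusted p = 0.00079). Both p-values are for the preset correlation. Within runs 2 and 3, each with 1 array per time, the list medians differed by -0.91 and -0.25. With an estimated correlation the difference itself did not pass in camera (adjusted p = 0.74), nor in fry (adjusted p = 0.68). The p-values above therefore hold only for the preset and do not exclude differences between runs. The small number at 8 h stays open as well: without sample 1 at 8 h, which leaves 1 array there, the median was -0.65 and the call was lost. A change with treatment time stays a hypothesis.

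The ribosomal protein list lay above 0 on 8 of 8 arrays. A bias shared by abundant transcripts could not be decided, since no signal intensities were used and abundance is unknown. The values show only that 2 lists differed. Housekeeping genes averaged -0.13 ± 0.24 (SD, 10 genes) against 0.17 ± 0.22 for 17 ribosomal genes. The 2-sided permutation p was 0.0028 (100000 resamples), with genes taken as independent, which they are not. The array medians of the housekeeping list averaged 0.061 in run 1, -0.34 in run 2 and -0.023 in run 3, so its fall came from run 2; without run 2 its genes averaged -0.012 ± 0.12 against 0.18 ± 0.075 for the ribosomal genes (SD; 2-sided permutation p = 7e-05). The arrays of run 1 as the source could not be decided: without them the median was 0.088 and no longer passed (adjusted p = 0.12), against 0.16 with them, and a dye bias of these genes was not tested.

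Over the 3 times the real signs gave 0 rows, so 100 of 100 sign flips of whole arrays had to give as many (the highest other gave 0), and this count decides nothing about chance. For 24 h against 12 h the 10 splits of the 6 arrays are too few for a share under 0.05. The real split gave 0 rows past the threshold and the highest other 1. At an unadjusted p under 0.05 the real split gave 40 rows and the highest other 437.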

How the results depend on the processing

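Leaving out a database run, the median over features of a gene, leaving out values of size over 4, leaving out CD74, and scale normalization with the run as a random block were added after the data were seen; the other alternatives were planned. The direction of 6 list results held under every alternative run: the NF-κB study list from -0.98 to -0.47, MHC class II from -0.47 to -0.16, the unfolded protein response from 0.029 to 0.23, ribosomal proteins from 0.027 to 0.22, and at 24 h against 8 h the study list from -1.09 to -0.37 and MHC class II from -0.84 to -0.30. Values as deposited and quantile normalization moved the median of all rows by -0.11 and -0.14 against the centred arrays. Signal over background is unknown, and 8 arrays of very different spread limit all counts. The cause of the changes below was not tested unless stated.

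Of 182 counts of rows (named genes or unnamed features) under an alternative 167 were 0, as with the centred arrays. Over the 3 times, 6 rows passed after quantile normalization, 2 with rows measured on 1 array at each time, 6 with the database run as a block and 10 without run 3, but 0 with the run as a random block or with 1 mean per run. At 8 h the counts were 10 with rows measured on 1 array and 22 without run 3, and at 24 h quantile normalization gave 5. For 12 h against 8 h they were 5 with rows on 1 array and 11 without run 3, and for 24 h against 8 h 3 and 11. With each array left out in turn the counts ranged from 0 to 58 over the 3 times, 0 to 131 at 8 h, 0 to 78 for 12 h against 8 h and 0 to 77 for 24 h against 8 h, and were 0 for the other comparisons. The high counts came without sample 1 at 8 h, which leaves a lone, widely spread array assumed to vary like the other times.

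The sample numbers did not pair the samples at 8 h with the later ones; between 12 h and 24 h the number and the run give the same pairs. Deviations from the time means of samples with the same number correlated at 0.20 to 0.33 between 12 h and 24 h (3 pairs) and at -0.26 to -0.15 between 8 h and the later times (4 pairs), where the deviations of the 2 arrays at 8 h mirror each other. Of the 8 arrays 5 correlated best with their own number and 8 with their own run. With the sample number as a replicate block 0 rows passed in each comparison, 4 lists passed over the 3 times, and at 24 h against 8 h 1 list passed, the study list at -0.63 having an adjusted p of 0.20.

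Of 28 lists 4 passed over the 3 times. The number was 7 after quantile normalization, scale normalization, features on their own or scale normalization with the run as a random block, 2 without run 3, 0 with an estimated correlation and 0 in fry; leaving out each array gave 2 to 6. At 24 h against 8 h 2 passed. That number was 4 after quantile normalization or without run 2, 1 with array weights, without run 1 or without run 3, 0 with an estimated correlation and 0 in fry, and 0 to 3 with each array left out.

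With an estimated correlation or in fry, which leave medians as they are, these calls were lost: the study list (-0.74), MHC class II (-0.26), the unfolded protein response (0.16), ribosomal proteins (0.16), and at 24 h against 8 h the study list (-0.62) and MHC class II (-0.58). Without run 3 MHC class II (-0.26, adjusted p = 0.23 in a range up to 0.47) and the unfolded protein response (0.18) lost theirs, and without run 1 the unfolded protein response (0.077) and ribosomal proteins (0.088). The study list at 24 h against 8 h lost its call with array weights (-0.45), without run 1 (-0.45) and without run 3 (-0.77). With each array left out the medians ranged from -0.32 to -0.18 for MHC class II, 0.11 to 0.20 for the unfolded protein response and 0.11 to 0.18 for ribosomal proteins. At 24 h against 8 h they ranged from -0.89 to -0.37 for the study list and -0.76 to -0.41 for MHC class II.

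The median of the NF-κB textbook list, 0.0091, turned to -0.088 on values as deposited, -0.21 after quantile and -0.056 after scale normalization, -0.039 with rows on all 8 arrays, -0.023 with rows on 1 array at each time, -0.029 with features on their own and -0.022 with array weights. It was -0.014, -0.098 and -0.11 without runs 1, 2 and 3, -0.032 after scale normalization with the run as a random block, and -0.073 to 0.080 with each array left out.

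Of 2023 values of named genes under an alternative 1980 kept direction and side of the threshold, 12 passed where they had not, and 31 turned sign. No named gene had passed with the centred arrays, so keeping its side meant staying uncalled, and this count is no measure of stability. Without run 2 the means were -0.018 for SDC4, 0.12 for SLAMF7, -0.025 for EBF1, -0.044 for SPIB, 0.026 for CBS, 0.054 for MCM4, 0.14 for CDT1, 0.33 for NCL, 0.15 for CDKN1A, -0.0039 for CCNG2, 0.041 for PSMD14, -0.12 for IL10, 0.090 for GATA3 and 0.30 for CD3D. After quantile normalization they were -0.017 for SPIB, 0.035 for NCL, -0.15 for HBG1 and -0.10 for KLF1. Scale normalization gave NCL 0.058, and 0.066 with the run as a random block; values as deposited gave HBG1 -0.011, and leaving out sizes over 4 gave CD3D 0.025. PSMB4 was at 0.0094 with the replicate block, the run as a block or array weights and at 0.13 without run 3. With each array left out PSMB4 ranged from -0.25 to 0.12, PSMD14 from -0.15 to 0.021 and CD3D from -1.52 to 0.29.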

Other observations

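These values were looked at after the data were seen, and no explanation is offered for them. Among 3460 rows with values on all 8 arrays, 45 lay below 0 on every array and 48 above, where independent arrays with the same shares of signs would give 10.8 and 13.2; arrays of a run are not independent, which raises such counts. Of the rows below 0 on 8 of 8 arrays 34 had a gene symbol, and 7 of them were genes of the NF-κB study list. Others included INPP4A at -1.23 ± 0.56 (SE), RGS16, a regulator of G protein signalling, at -0.79 ± 0.20, and ADAM8, a surface metalloprotease, at -0.50 ± 0.13. PIM1, a survival kinase, was at -0.42 ± 0.19. The anti-apoptotic gene BCL2 was at -0.35 ± 0.15, and the pro-apoptotic gene BAD at -0.36 ± 0.17. The genes named in these observations followed no rule fixed beforehand.

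Of the rows above 0 on 8 of 8 arrays 32 had a symbol. They included SSR3 at 0.64 ± 0.15, JAG1, a Notch ligand, at 0.56 ± 0.19, EEF1B2, a translation elongation factor, at 0.49 ± 0.18, SETD7, a lysine methyltransferase, at 0.44 ± 0.13, BMP6, a secreted growth factor of the TGF-β family, at 0.40 ± 0.13, and PRDM1, the plasma cell regulator BLIMP-1, at 0.32 ± 0.12. None passed over all rows in limma, the adjusted p being 0.87 for each gene named here.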
